A study of Mus musculus with 9 samples.

How the data were processed

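Retinal mRNA was measured on 9 Affymetrix Mouse Genome 430 2.0 arrays, 3 for each of 3 groups of female mice: controls kept in a dark environment and mice under white light-emitting diodes (LEDs) with a correlated colour temperature of 2954K or 7378K. Per the labels, exposure lasted 14 days with 12 h of light and 12 h without, at an illuminance of 1000 lx in both LED groups. The labels give the controls the same hours and no illuminance, so the light in their environment is not known. Each array came from a pool of 3 right-eye retinas, so that 1 array stood for 1 pool and n = 3 pools per group. Per the labels, RNA was extracted with mirVana PARIS, its integrity was checked on a Bioanalyzer and it was labelled with the GeneChip 3' IVT PLUS kit. Integrity values, scan dates and hybridisation batches were not analysed here.

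The deposited table held 45101 probe sets with 0 missing values. Per the submitters' processing notes, which name MAS5 and the Bioconductor package affy without a version, a role or an order, the values were MAS5-type signals per probe set, and the deposited values were on a log2 scale. The scale was checked on the values: 2 raised to the value had a 2% trimmed mean of 500 on each of the 9 arrays, whereas natural logarithms would have given trimmed means of 13250 to 13870. The deposited values had been scaled array by array to this common mean, with no normalisation of their distributions between arrays, and they were used without further scaling. Signal over background was not recorded, because no detection calls were used, and the number of arrays limits the precision.

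Probe sets were assigned to genes with the annotation of the array platform. Of the 45101 probe sets, 64 were controls, 34945 had 1 gene symbol, 932 had several symbols and 9160 had none. Of the 34945, 34741 were matched by gene identifier to the RefSeq annotation of mouse genome build GRCm38.p6, with no change of symbol. Each of 18193 genes was represented by the single-symbol probe set with the highest mean over the 9 arrays. Genes with a mean below the 40th percentile of the probe set means (5.91 on the log2 scale) were left out as dim, which left 12765 genes.

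A linear model with 1 mean per group was fitted to all 9 arrays (6 residual degrees of freedom) with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, and eBayes with an intensity trend), with the R package data.table, version 1.17.8, to read the values. Contrasts were 2954K against control, 7378K against control, 7378K against 2954K, and the mean of both LED groups against control. P values were adjusted by Benjamini-Hochberg over the 12765 genes within each contrast, and a gene was called changed at an adjusted p under 0.05. Figures were drawn with matplotlib 3.10.9.

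The contrasts, the filter, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. Of 31 gene lists (retinal cell types, pathways and tissues that could be carried over during dissection), 30 had at least 5 measured genes and were tested. The erythrocyte list had 0 measured genes and was not tested. Lists were tested with limma's camera, which compares a list with all other genes, at a preset inter-gene correlation of 0.01, adjusted over the 30 lists of a contrast. Camera with an estimated correlation per list and the self-contained test fry were run beside it. Some genes belong to several lists: C1qa, C1qb and C1qc, for example, stand in both the microglia and the complement list.

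Named genes followed a fixed rule. For each contrast it took the 6 largest rises and the 6 largest falls among changed genes whose replicates did not overlap between groups, without predicted genes. In a direction with none, it took the 3 genes with the smallest unadjusted p. It added up to 4 members with the smallest p from each list described, and a fixed panel of Gnat1, Sag, Opn1sw, Opn1mw, Arr3, Gfap, Edn2, Fgf2, Stat3, Cp, Hmox1 and Aif1. A pair of further genes of the panel was not analysed here, and Fgf2 lay below the intensity filter, so that only its values are given. Where a control mean lay below the filter value, fold changes are given as bounds against that value.

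RNA and labelling quality was read from the control probe sets as the 3' minus 5' log2 difference, averaged over Gapdh and beta-actin, with the same difference for the dap spike-in, a bacterial transcript added for the labelling. Group means were compared by two-sided exact permutation tests, in which 3 against 3 arrays cannot give a p below 0.1. The similarity of the LED effects was set beside 100 simulated unchanged sets that shared the same controls. Recovery was tested on simulated data with the fitted spread. With 200 of 12765 genes changed, the share called in 7378K against 2954K over 20 runs was 21.3% at 0.5, 75.7% at 1 and 93.1% at 2 on the log2 scale, and genes left unchanged made up 6.06% of the calls. The simulated errors were independent, with 1 spread per gene for all groups and no structure of the arrays. Recovery in the measured arrays may therefore be lower.

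Alternatives covered the intensity filter (none or the 60th percentile), the probe set chosen for a gene, quantile normalisation, median centring, array weights, eBayes without a trend or in its robust form, fits of only the groups compared, an unadjusted p under 0.05 with a 1.5-fold change, and leaving out each array. Added after the data were seen were leaving out 2 arrays together, covariates for the 3' minus 5' difference and for the lens genes, quantile normalisation for the quality measure and the size of the response over the changed genes. Probe sets without a gene symbol stood outside the gene comparisons.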

Results

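The tissue was described as neurosensory retina, separated from the pigment epithelium, of female BALB/c mice (written Babl/c in the labels) aged 10 weeks. The pigment epithelium gene Rpe65 nevertheless gave a high signal on all 9 arrays, from 9.73 in control 2 to 11.83 in 2954K 2, so the separation was not complete by this measure. BALB/c mice are albino, so their eyes lack the pigment that screens light. Of 9 arrays, 3 came from controls in a dark environment, 3 from mice under warm white LED light of 2954K and 3 from mice under cold white LED light of 7378K, each from a pool of 3 retinas. The labels give the controls a cycle of 12 h on and 12 h off like the LED groups and no illuminance, so the light they met is not known. Arrays are named by group and replicate number. The median signal of the arrays lay between 6.77 and 7.03 on the log2 scale. Pearson correlations of signal across the 12765 genes, which are not independent replicates, were 0.953 to 0.980 between arrays of a group and 0.941 to 0.974 between groups.

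Some arrays differed in the 3' minus 5' signal of control probe sets and in transcripts of neighbouring tissues. The 3' minus 5' difference of Gapdh and beta-actin, which grows when 5' ends are lost in degradation or labelling, was 0.33, 0.20 and 0.42 in controls 1 to 3. It was 2.78, 0.21 and 1.05 in the 2954K arrays and 1.80, 1.67 and 1.55 in the 7378K arrays. The mean difference from control was 1.36 for 7378K (exact two-sided permutation p = 0.1, BH-adjusted p = 0.3 over 12 tests) and 1.03 for 2954K (exact p = 0.3, BH-adjusted p = 0.533), where 0.1 is the smallest p that 3 against 3 arrays allow. Crybb2, a lens crystallin, reached 14.75 in control 3, 12.63 in 2954K 3 and 9.99 in 7378K 3, and lay between 3.08 and 7.69 in the other 6 arrays. Tyrp1, a melanocyte and pigment epithelium gene, was also higher in the third array of each group, at 10.40 in control 3, 12.15 in 2954K 3 and 9.41 in 7378K 3.

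**Figure D1:**
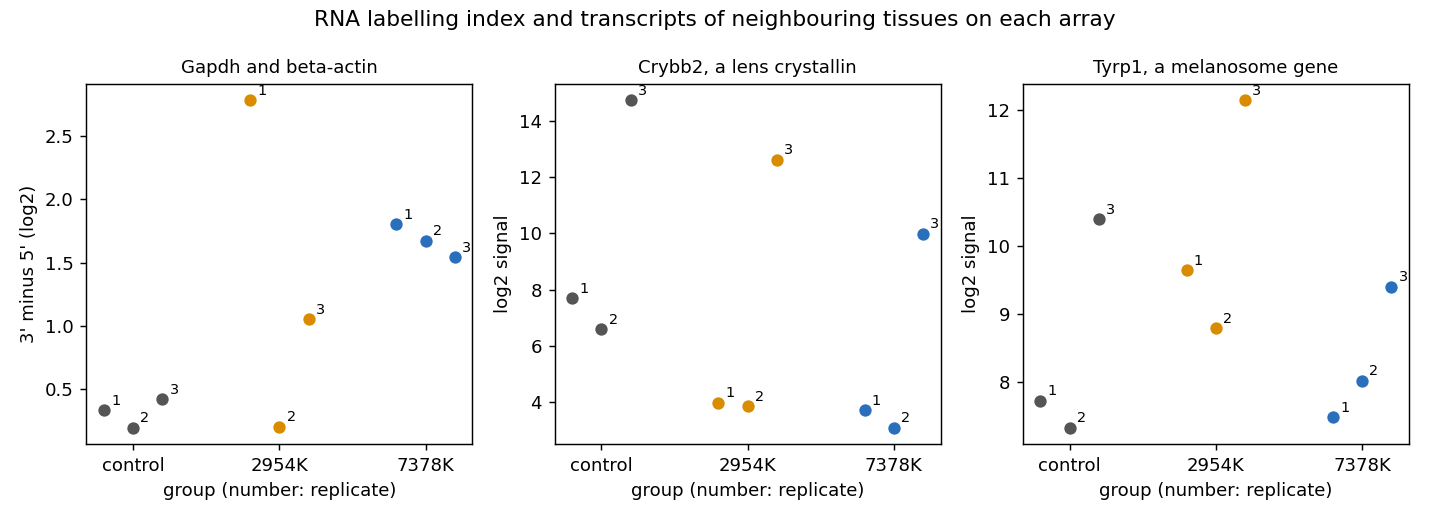
Each point is 1 array, grouped on the x axis as control, 2954K or 7378K, and the y axes give, in log2 units, the 3' minus 5' difference of Gapdh and beta-actin, the signal of the lens gene Crybb2 and the signal of the pigment cell gene Tyrp1. The 3 arrays of 7378K lie between 1.55 and 1.80 in 3' minus 5' difference, and Crybb2 is highest in control 3 at 14.75.

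The first comparison asked how the retina under warm white light of 2954K differed from that of mice in the dark environment. Genes of reactive gliosis and photoreceptor stress signalling, microglia, complement and the interferon response were higher under 2954K light as lists. With an estimated correlation the first 2 of these lists passed, and complement (adjusted p = 0.095) and interferon (adjusted p = 0.117) did not. Edn2, which encodes the vasoactive peptide endothelin 2, rose 37.8-fold, from 7.5 ± 0.87 to 12.74 ± 0.19 (log2 signal, mean ± SD, n = 3). Fgf2os, an antisense transcript of the fibroblast growth factor 2 gene, rose 16.1-fold, from 6.34 ± 0.18 to 10.35 ± 0.35. The rod transcripts Gnat1 (rod transducin) and Sag (rod arrestin) showed no change past the test, with a difference of -0.03 for Gnat1 (95% confidence interval -0.36 to 0.30). Both lay near the highest signal of each array (14.96 to 15.42), where a change of the transcript can go unseen, so they do not show that these genes were stable.

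In limma, 156 of 12765 genes changed under 2954K light, of which 132 rose and 24 fell, and 70 of the rises and 5 of the falls were at least 2-fold. An unadjusted p under 0.05 was reached by 1667 genes, where 638 were expected without any change. The groups did not overlap for 1941 genes (15.2%, where chance gives 10%). The count of changed genes was 85 without control 1, 79 without control 2, 895 without 2954K 2 and 81 without 2954K 3, and 103 without control 3 and 2954K 3 together. With the 3' minus 5' difference as a covariate it was 102, with 92 risen and 10 fallen. That covariate ended the calls of 10 of the 31 named genes called, namely C1qc, Bst2, Aif1, Ccn1, Junb, Aqp4, Col4a3, Taf4b, Glb1l3 and Dleu7. The difference of the dap spike-in, used in its place, ended 8 of these calls, all but those of Junb and Glb1l3.

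Among 21 measured genes of reactive gliosis and photoreceptor stress signalling, 9 rose, 0 fell and 12 did not pass (16 risen when adjusted over the list alone). Cebpd, a transcription factor of acute-phase genes, rose 15.8-fold (adjusted p = 9.7e-07), and Socs3, a feedback inhibitor of JAK-STAT signalling, rose 10.1-fold (adjusted p = 3.8e-06). Stat3, the transcription factor of that pathway, rose by 1.54 ± 0.10 (SE) on the log2 scale (adjusted p = 3.8e-06). Bcl3, an atypical inhibitor of NF-kB signalling, was at least 7.08-fold higher (adjusted p = 0.00023), its control mean of 2.71 being below the intensity filter. Gfap, the intermediate filament of reactive glia, measured 6.77 ± 0.57 in control and 7.76 ± 0.08 under 2954K light (adjusted p = 0.13), and Cp, ceruloplasmin, measured 10.57 and 11.80 (adjusted p = 0.12). The list was higher than other genes, with a median difference of 1.54 (camera adjusted p = 7.5e-26, and adjusted p = 0.024 with an estimated correlation).

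Of 18 microglia and macrophage genes, 10 rose, 0 fell and 8 did not pass (14 risen when adjusted over the list alone), with a median difference of 1.48 (camera adjusted p = 5.4e-20, and adjusted p = 0.024 with an estimated correlation). Ctss, a lysosomal protease, rose 3.01-fold, Ly86, a partner of a Toll-like receptor homologue, 3.57-fold, and C1qa and C1qb, chains of the complement initiator C1q, 4.98-fold and 4.38-fold. C1qc, the remaining chain, was at least 6.48-fold higher and Aif1, the microglial calcium-binding protein IBA1, at least 2.21-fold higher. Of 7 complement genes 4 rose and 0 fell (5 risen when adjusted over the list alone), among them Cfi, a protease that limits complement, by 3.01-fold (camera adjusted p = 5.3e-09, and adjusted p = 0.095 with an estimated correlation). Of 21 interferon response genes 3 rose and 0 fell (11 risen when adjusted over the list alone): B2m, the light chain of MHC class I, rose 3.23-fold, Gbp2, an interferon-induced GTPase, 4.05-fold, and Bst2, an antiviral membrane protein, was at least 4.42-fold higher (camera adjusted p = 2.4e-09, and adjusted p = 0.117 with an estimated correlation). Of 14 chemokine and cytokine genes 0 rose (3 when adjusted over the list alone), with a camera adjusted p of 0.041 that became 0.146 without control 1, 0.163 without 2954K 2 and 0.145 without 2954K 3, and 0.456 with an estimated correlation. The call of C1qc ended in 6 of the 9 fits that left out 1 array (up to an adjusted p of 0.136 without 2954K 3), that of Aif1 in 7 (0.159 without control 2) and that of Bst2 in 2 (0.111 without 2954K 3).

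In the antioxidant and metal stress list the metallothionein genes Mt2 and Mt1 rose 2.86-fold (adjusted p = 0.00099) and 2.57-fold, and 21 of the 23 genes did not pass (3 risen when adjusted over the list alone; camera adjusted p = 0.0017, and 0.456 as the adjusted p with an estimated correlation). Hmox1, heme oxygenase, measured 4.94 in control and 6.40 under 2954K light (adjusted p = 0.15). Of 28 unfolded protein response genes only Atf3, a stress-induced transcription factor, rose, by 3.89-fold (3 risen when adjusted over the list alone), with a camera adjusted p of 0.0059, which was 0.086 without 2954K 3 and 0.316 with an estimated correlation. Of 19 immediate early genes 3 rose (3 when adjusted over the list alone; 1 with the covariate), the AP-1 genes Junb by 2.22-fold and Jun by 1.56-fold and the matrix protein gene Ccn1 by 2.29-fold (camera adjusted p = 0.0085, 0.066 without control 1 and 0.107 without 2954K 3, and adjusted p = 0.289 with an estimated correlation). Of 17 Müller glia genes 2 rose (4 when adjusted over the list alone; 1 with the covariate), Crym, a thyroid-hormone-binding protein, by 2.33-fold and Aqp4, a water channel, by 1.48-fold (camera adjusted p = 0.00065, and adjusted p = 0.095 with an estimated correlation). For the heat shock list, 0 of 12 genes passed and the camera adjusted p was 0.032, which was 0.096 without control 1, 0.215 without 2954K 3, 0.116 with the covariate and 0.456 with an estimated correlation. The calls of Junb, Jun, Ccn1 and Aqp4 ended in 2, 7, 5 and 5 of the 9 fits that left out 1 array, up to an adjusted p of 0.159 for Aqp4 without control 2.

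Rod genes showed small differences as a list, and Gnb3, a gene of the cone list, showed a larger one. Pools of retinas were measured, so the values do not tell which cells held the Gnb3 transcript. As a list, 29 rod genes were lower, with a median difference of -0.16 and 27 of 29 below control (camera adjusted p = 1.9e-05, and adjusted p = 0.331 with an estimated correlation), although 0 of them fell by the gene test, also when adjusted over the list alone. Of 14 cone genes, Gnb3, a cone transducin subunit, rose 1.97-fold (adjusted p = 0.00023) and 0 fell by the test over all genes (1 risen and 1 fallen when adjusted over the list alone; camera adjusted p = 0.983). The cone opsin Opn1mw measured 10.84 in control and 10.23 under 2954K light (adjusted p = 0.10), Opn1sw 13.74 and 13.62 (adjusted p = 0.67), and cone arrestin Arr3 11.98 and 11.47 (adjusted p = 0.42). Fgf2 measured 3.50 ± 1.16 in control, 5.85 ± 1.30 under 2954K light and 5.66 ± 0.11 under 7378K light and was not tested.

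The largest falls under 2954K light were led by Prss56, a trypsin-like serine protease, from 8.46 ± 0.15 to 5.47 ± 0.64 (adjusted p = 0.0047). The latter mean lay below the intensity filter, so the size of this fall is uncertain. Glb1l3, a beta-galactosidase-like gene, fell by 1.4, Dleu7 fell by 1.43, Taf4b, a subunit of a general transcription factor, fell by 1.20, Col4a3, a basement membrane collagen, fell by 1.02 and Pdzph1 fell by 0.90 on the log2 scale. The calls of Glb1l3, Dleu7, Taf4b and Col4a3 ended in 3, 3, 7 and 7 of the 9 fits that left out 1 array, with adjusted p up to 0.204 for Col4a3 without 2954K 3. Lists of neighbouring tissue moved too, without a single gene past the test. Pigment epithelium and melanocyte genes were higher (median 0.81, camera adjusted p = 0.0162, and adjusted p = 0.632 with an estimated correlation), with an adjusted p of 0.146 without control 1, 0.212 without control 2, 0.058 without 2954K 2 and 0.092 with the dap spike-in as the covariate. Extraocular muscle genes were lower (median -0.75, camera adjusted p = 0.041, and adjusted p = 0.586 with an estimated correlation), with 0.674 without control 3, 0.158 without 2954K 3 and 0.085 without 2954K 2. Glycolysis genes were lower (median -0.13, camera adjusted p = 0.044, and adjusted p = 0.632 with an estimated correlation; 1 risen and 1 fallen when adjusted over the list alone), with 0.396 without control 3, 0.313 without 2954K 2, 0.086 without 2954K 3 and 0.056 without 7378K 1. The remaining 16 lists had camera adjusted p of 0.0988 to 0.983.

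**Figure D2:**
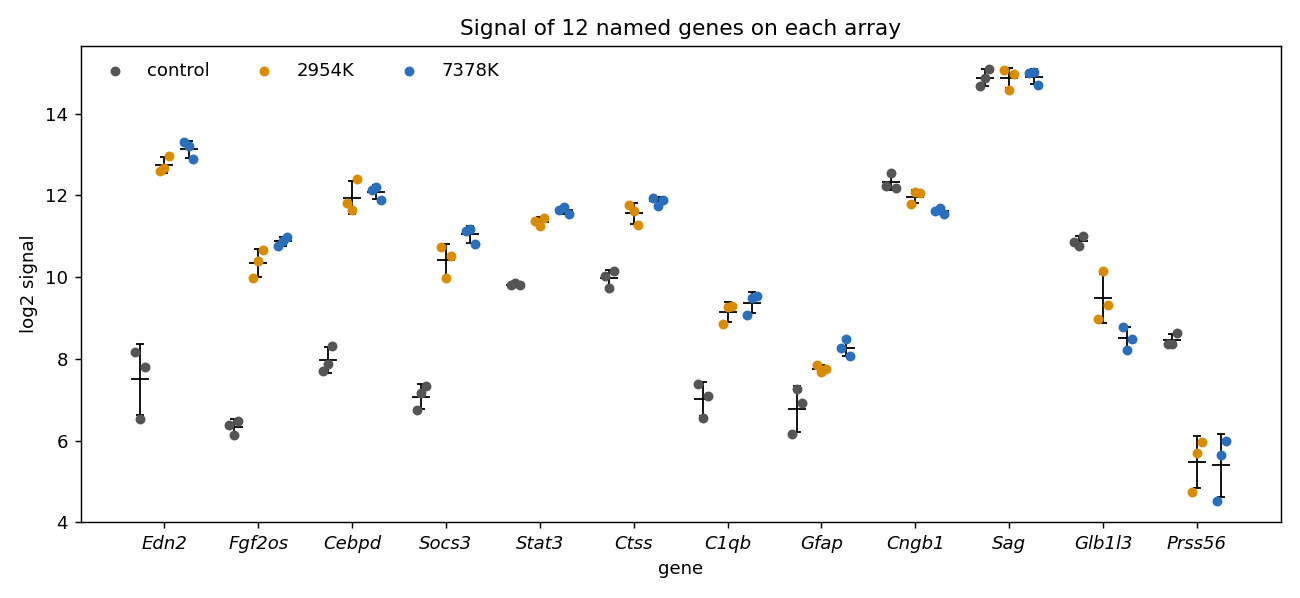
The x axis lists 12 named genes and the y axis gives their log2 signal; points are single arrays coloured by group (control, 2954K or 7378K, n = 3 each) and bars give the mean ± SD. Edn2 lies at 7.5 ± 0.87 in control and at 12.74 ± 0.19 and 13.13 ± 0.21 in the LED groups.

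The second comparison set cold white light of 7378K against the same controls. Gliosis and stress signalling, microglial, complement, interferon and chemokine genes were higher, and rod photoreceptor and cholesterol synthesis genes were lower, as lists in camera. With an estimated correlation none of these lists passed (adjusted p = 0.063 for gliosis and microglia and 0.20 for the others). Edn2 rose 49.5-fold, to 13.13 ± 0.21 (n = 3), Fgf2os 23.2-fold, to 10.87 ± 0.10, Cebpd 17.3-fold and Socs3 15.7-fold. Rod genes fell by less, Prph2, a structural protein of outer segment discs, by 1.74-fold and Cngb1, a subunit of the rod cation channel, by 1.64-fold. The 3' minus 5' difference moved with this comparison, at 1.67 ± 0.13 in the 7378K arrays and 0.32 ± 0.12 in the controls (SD, n = 3).

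By the gene test, 449 of 12765 genes changed, 301 risen and 148 fallen, with 119 of the rises and 28 of the falls at least 2-fold. An unadjusted p under 0.05 was reached by 2883 genes, where 638 were expected, and the groups did not overlap for 4645 genes (36.4%, where chance gives 10%). With the 3' minus 5' difference as a covariate, 111 genes rose and 25 fell, with that of the dap spike-in 66 rose and 11 fell, and with the mean of a gene's probe sets 128 rose and 127 fell. The covariate ended the calls of 24 of the 49 named genes called, namely C1qc, Bst2, Egr3, Icam1, Gfap (adjusted p = 0.132), Aif1, Mt1, Cp, Vcam1, Ccn1, Clu, Hk1, Xbp1, Aqp4, Isl1, Hk2, Cnga1 (0.054), Cngb1 (0.097), Prph2 (0.079), Mvd, Fdps, Nnat, Slc25a25 and Prss56 (0.069). The dap covariate ended 31, these and B2m (adjusted p = 0.077), Gbp2 (0.087), Cfi (0.147), Ccl12 (0.082), Junb (0.071), Col4a3 (0.097) and Dleu7 (0.148). The count was 188 without control 1, 170 without control 2, 1517 without 2954K 1, 1211 without 2954K 2, and 144, 180 and 169 without 7378K 1, 2 and 3.

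Of 21 genes of reactive gliosis and photoreceptor stress signalling, 13 rose, 0 fell and 8 did not pass (18 risen when adjusted over the list alone), with a median difference of 1.67. With the 3' minus 5' difference as a covariate, 8 of them rose and the median was 1.94 (camera adjusted p = 9.1e-27). With the dap covariate 7 rose. Stat3 rose by 1.82 on the log2 scale, from 9.81 ± 0.03 to 11.64 ± 0.09 (adjusted p = 7.8e-07), and Bcl3 was at least 12.6-fold higher (adjusted p = 5.2e-05). Gfap rose 2.84-fold, to 8.28 ± 0.20 (adjusted p = 0.011, and up to 0.062 without 7378K 2), and Cp 2.55-fold (adjusted p = 0.048, and up to 0.185 without control 2). The camera adjusted p of the list was 5.5e-20, and the adjusted p with an estimated correlation was 0.063.

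Microglia and macrophage genes rose in 11 of 18 cases, with 0 fallen and 7 not past the test (15 risen when adjusted over the list alone), and in 7 cases with the 3' minus 5' difference as a covariate. Their median difference was 1.57, and 1.51 with the covariate (camera adjusted p = 1.5e-13, and adjusted p = 0.063 with an estimated correlation). Ctss rose 3.70-fold, Ly86 4.99-fold, C1qa 5.21-fold and C1qb 5.13-fold. C1qc was at least 6.06-fold and Aif1 at least 1.91-fold higher. Of 7 complement genes 5 rose (5 when adjusted over the list alone; 3 with the covariate), Cfi by 2.91-fold (camera adjusted p = 5.5e-06, and adjusted p = 0.20 with an estimated correlation). Their median was 1.88, and 1.95 with the covariate. Of 21 interferon response genes 4 rose (12 when adjusted over the list alone; 3 with the covariate), B2m by 2.96-fold, Gbp2 by 4.45-fold, Irf9, a transcription factor of interferon signalling, by 1.86-fold, and Bst2 by at least 4.76-fold (camera adjusted p = 1.5e-05, and adjusted p = 0.20 with an estimated correlation). The median of the list was 0.72, and 0.87 with the covariate. Of 14 chemokine and cytokine genes 3 rose (5 when adjusted over the list alone; 1 with the covariate): Ccl12, a monocyte chemoattractant, was at least 2.69-fold and Icam1, an adhesion molecule of leukocytes, at least 2.37-fold higher, and Vcam1, also an adhesion molecule, rose 2.13-fold, although its log2 difference was -0.27 with the mean of its probe sets (camera adjusted p = 0.0029, and adjusted p = 0.20 with an estimated correlation). That list had a median of 0.64, and 0.98 with the covariate. With the dap covariate 5 microglia and macrophage genes, 2 complement genes, 1 interferon response gene (Irf9, not B2m, Gbp2 or Bst2) and 0 chemokine and cytokine genes rose. The calls of C1qc, Aif1, Bst2, Irf9, Vcam1 and Icam1 ended in 4, 6, 1, 6, 3 and 6 of the 9 fits that left out 1 array, up to an adjusted p of 0.164 for Aif1 without 7378K 1.

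Rod genes fell in 5 of 29 cases, with 0 risen and 24 not past the test (9 fallen when adjusted over the list alone), and in 2 cases with the 3' minus 5' difference as a covariate. Cnga1 and Cngb1, the subunits of the rod cation channel, fell by 0.49 (adjusted p = 0.009) and by 0.71 (adjusted p = 0.0068) on the log2 scale. Prph2 fell by 0.80, from 13.78 to 12.98 (adjusted p = 0.027), and Reep6, a rod endoplasmic reticulum protein, fell by 0.53 (adjusted p = 0.032). The median difference of the list was -0.25 (camera adjusted p = 4.5e-08, and adjusted p = 0.20 with an estimated correlation). With the covariate it was -0.33 (camera adjusted p = 3.6e-17). Gnat1 differed from control by 0.03 (95% confidence interval -0.30 to 0.36; adjusted p = 0.92), and Sag measured 14.88 and 14.90. The calls of Cnga1, Prph2 and Reep6 ended in 2, 6 and 5 of the 9 fits that left out 1 array, with adjusted p of 0.076, 0.131 and 0.166 without 7378K 1. Of 14 cone genes, Gnb3 rose 2.03-fold and 0 fell (1 risen and 1 fallen when adjusted over the list alone; camera adjusted p = 0.997). Opn1mw measured 10.84 in control and 10.33 (adjusted p = 0.088), Opn1sw 13.74 and 13.57 (adjusted p = 0.38), and Arr3 11.98 and 11.28 (adjusted p = 0.14).

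Of the 16 cholesterol synthesis genes 2 fell, Mvd, which makes isopentenyl diphosphate, by 2.17-fold and Fdps, which makes farnesyl diphosphate, by 2.69-fold, and 14 did not pass (3 fallen when adjusted over the list alone; 0 with the 3' minus 5' difference as a covariate). The list had a median of -0.21 (camera adjusted p = 0.00062, and adjusted p = 0.20 with an estimated correlation). With the covariate its median was -0.22 (camera adjusted p = 0.00017). In 2954K 1, 2 and 3, Fdps measured 8.98, 10.90 and 10.10, beside 9.25 to 9.66 in 7378K and 10.75 to 11.16 in control. Mvd measured 7.70, 8.26 and 7.94 there. Under the same light both were thus lowest in 2954K 1, with the highest 3' minus 5' difference, and highest in 2954K 2, with the lowest. Of 19 immediate early genes 4 rose (8 when adjusted over the list alone; 2 with the covariate), Junb by 2.70-fold, Jun by 1.66-fold, Ccn1 by 1.99-fold and Egr3, an activity-regulated transcription factor, by at least 2.28-fold (camera adjusted p = 0.0054, and adjusted p = 0.20 with an estimated correlation). Their median was 0.48, and 0.26 with the covariate. Of 17 Müller glia genes Crym rose 2.73-fold, Aqp4 1.49-fold and Clu, an extracellular chaperone, 1.90-fold (7 risen when adjusted over the list alone; 1 with the covariate, with a median of 0.21 before and 0.26 with it; camera adjusted p = 0.0070, and adjusted p = 0.20 with an estimated correlation). Of 28 unfolded protein response genes Atf3 rose 4.28-fold and Xbp1, a transcription factor of the response, 1.5-fold (8 risen and 1 fallen when adjusted over the list alone; 1 risen with the covariate, with a median of 0.15 before and 0.14 with it), although the log2 difference of Xbp1 was -0.26 with x_at and s_at probe sets left out. The camera adjusted p of that list was 0.039, and 0.053 without control 1, 0.093 without control 3, 0.053 without 2954K 1 and 0.060 without 7378K 1, and the adjusted p with an estimated correlation was 0.421. The calls of Mvd, Fdps, Jun, Ccn1, Egr3, Aqp4, Clu and Xbp1 ended in 6, 7, 2, 6, 7, 3, 5 and 5 of the 9 fits that left out 1 array, up to an adjusted p of 0.186 for Egr3 without 7378K 1.

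Further named genes lay in lists that did not pass. Mt2 rose 3.21-fold and Mt1 2.55-fold, while Hmox1 measured 4.94 and 6.39 (adjusted p = 0.078). Of the glycolytic hexokinases, Hk1 rose 1.60-fold and Hk2 fell by 0.42 on the log2 scale, and Isl1, a transcription factor of bipolar and other inner retinal neurons, rose 1.38-fold. With the mean of the probe sets the log2 difference had the opposite sign, at -0.58 for Hk1 and -0.11 for Isl1. The largest falls were those of Prss56, to 5.39 ± 0.77 (adjusted p = 0.0024), Glb1l3, from 10.88 ± 0.12 to 8.50 ± 0.28 (adjusted p = 0.00022), and Dleu7, which fell by 1.81. For Prss56 the mean under 7378K light lay below the intensity filter. Slc25a25, a mitochondrial ATP carrier, fell by 1.63, Nnat, a membrane protein of neurons, fell by 1.52 and Col4a3 fell by 1.52. In 2954K 1, 2 and 3, Slc25a25 measured 7.52, 9.30 and 8.76, beside 8.05 to 8.51 in 7378K. Hk1 measured 13.77, 13.21 and 13.46 there, beside 13.56 to 13.75. Both were in the order of the 3' minus 5' difference within 2954K. Isl1, Glb1l3 and Nnat were in that order too, while Mt1, Mt2, Hk2, Prss56, Dleu7 and Col4a3 were not. The calls of Hk1, Hk2, Isl1, Slc25a25 and Nnat ended in 3, 6, 6, 6 and 5 of the 9 fits that left out 1 array, up to an adjusted p of 0.136 for Hk2 without 7378K 1. Those of Mt1, Hk1, Hk2, Isl1, Prss56, Slc25a25 and Nnat ended with the 3' minus 5' covariate, and those of Dleu7 and Col4a3 with the dap covariate. Crystallin and lens genes were lower, with a median of -2.48 and 0 of 13 past the gene test (camera adjusted p = 0.042, and adjusted p = 0.758 with an estimated correlation). Without control 3, in which Crybb2 was 14.75, their median was 0.02 (adjusted p = 0.673), and the call also ended without 2954K 1 (0.068), 2954K 2 (0.053), 7378K 1 (0.0997) and 7378K 2 (0.177) and with the 3' minus 5' covariate (0.239). The remaining 19 lists had camera adjusted p of 0.0608 to 0.997.

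**Figure D3:**
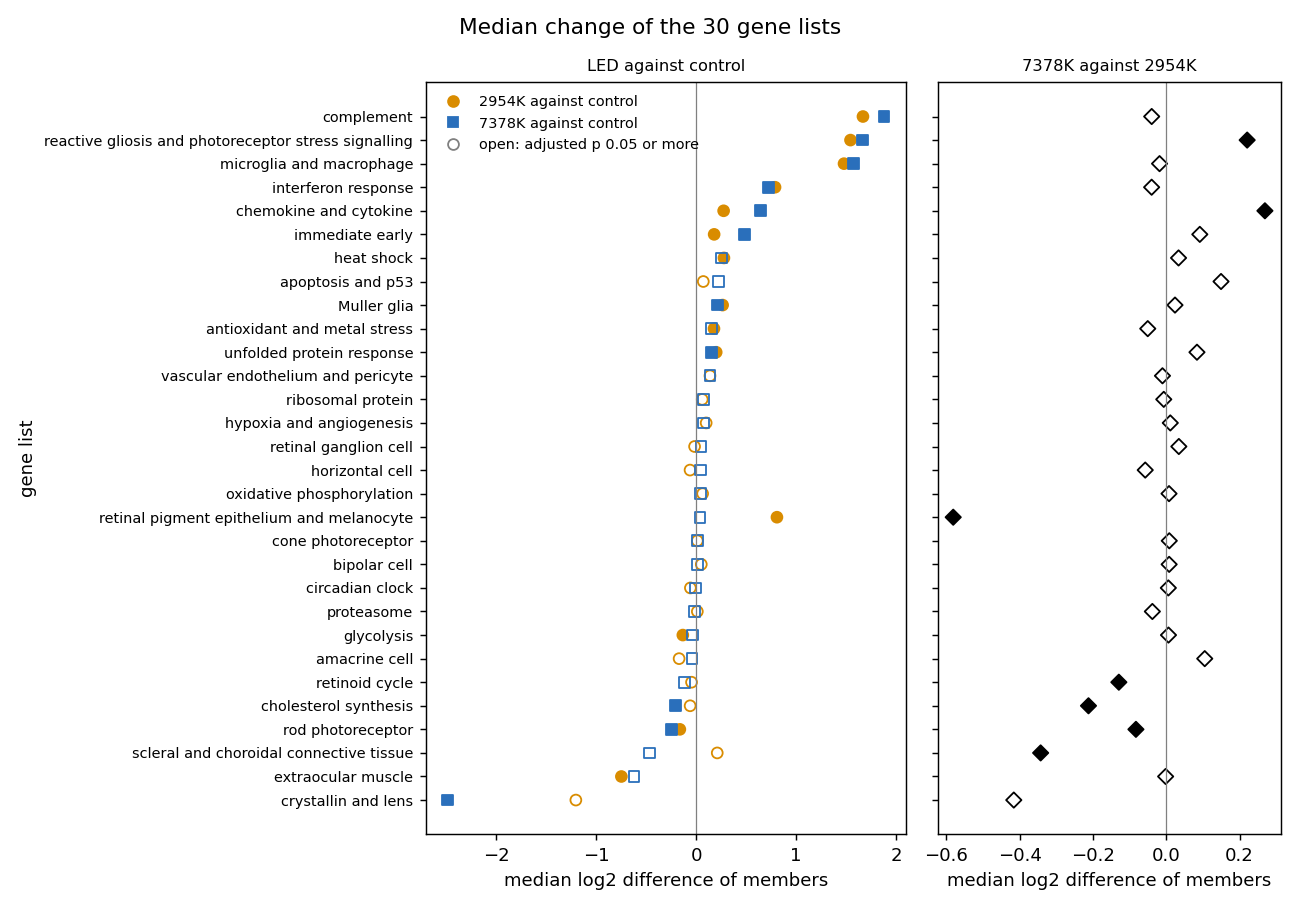
Each line is 1 gene list and the x axis gives the median log2 difference of its genes, on the left for each LED group against control and on the right for 7378K against 2954K; filled points passed camera at an adjusted p under 0.05. Reactive gliosis and photoreceptor stress signalling lies at 1.54 for 2954K and 1.67 for 7378K.

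The third comparison asked whether the retina differed between the 2 colour temperatures at the same illuminance. No single gene was told apart between 7378K and 2954K light: limma called 0 of 12765 genes (smallest adjusted p = 0.978), and 519 genes had an unadjusted p under 0.05, where 638 were expected. Edn2 differed by 0.39 (95% confidence interval -0.30 to 1.08), Stat3 by 0.28 (0.07 to 0.49) and Gfap by 0.51 (-0.08 to 1.10) on the log2 scale, each with an adjusted p of 0.98. As lists, cholesterol synthesis, pigment epithelium and melanocyte, rod, scleral and choroidal and retinoid cycle genes were lower under 7378K light, and gliosis and chemokine genes were higher. None of these lists passed with an estimated correlation (lowest adjusted p = 0.667) or with fry, and the calls of all but cholesterol synthesis and pigment epithelium and melanocyte ended with 1 array left out. The 3' minus 5' difference was 1.67 ± 0.13 in the 7378K and 1.35 ± 1.31 in the 2954K arrays (SD, n = 3).

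The genes with the smallest unadjusted p did not pass. Tnfaip3, which encodes the NF-kB inhibitor A20, measured 11.93 ± 0.14 under 2954K and 11.28 ± 0.09 under 7378K light, Fam3c, a secreted factor, 12.35 and 11.94, and Map7, a microtubule-associated protein, 12.30 and 11.84. In the other direction, Prtg, a membrane protein of the immunoglobulin superfamily, measured 9.53 and 10.22, Rian, an imprinted noncoding RNA, 8.55 and 9.23, and Pacs1, a sorting protein, 9.06 and 9.63. The photoreceptor genes Gnat1, Opn1mw, Opn1sw and Arr3 differed by 0.06, 0.10, -0.05 and -0.19, with adjusted p of at least 0.978. Gfap and Cp passed against control under 7378K light and not under 2954K light, but neither differed between the LED groups by this test. The groups did not overlap for 1092 genes (8.55%, where chance gives 10%), the median half-width of the 95% intervals was 0.35 on the log2 scale, and 29 genes were called without 2954K 1.

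The list tests held 0 genes past the gene test and none passed with an estimated correlation, where the lowest adjusted p was 0.667, or with fry. Cholesterol synthesis genes had a median of -0.21 with 14 of 16 lower, and pigment epithelium and melanocyte genes one of -0.58 with 13 of 14 lower, both at a camera adjusted p of 2.89e-05. Rod genes had a median of -0.08 with 22 of 29 lower (adjusted p = 0.000525), which was 0.276 without 2954K 1. Scleral and choroidal connective tissue genes had a median of -0.34 (adjusted p = 0.0160), which was 0.133 without 2954K 1, 0.620 without 2954K 3 and 0.088 without 7378K 2. Gliosis and stress signalling genes had a median of 0.22 with 18 of 21 higher (adjusted p = 0.0231), which was 0.587 without 2954K 1, 0.078 without 2954K 2, 0.062 without 7378K 1 and 0.088 without 7378K 2. Chemokine and cytokine genes had a median of 0.27 with 13 of 14 higher (adjusted p = 0.0259), which was 0.550 without 2954K 1, 0.095 without 7378K 1 and 0.088 without 7378K 2. Retinoid cycle genes had a median of -0.13 with 12 of 15 lower (adjusted p = 0.0293), which was 0.361 without 2954K 1, 0.158 without 2954K 2, 0.189 without 7378K 1 and 0.182 without 7378K 2. When adjusted over the list alone, 1 cholesterol synthesis gene and 1 connective tissue gene fell and 1 immediate early gene rose, and the remaining 23 lists had camera adjusted p of 0.0681 to 0.939. Tyrp1 and Dct, pigment cell genes, were highest in 2954K 3 at 12.15 and 13.22.

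The size of the response, a measure added after the data were seen, was taken over the 441 genes changed in the mean of both LED groups against control. These genes need not pass under each light. The response was 0.87 under 2954K and 1.02 under 7378K light on the log2 scale, counted in the direction of each gene's change. The mean difference of 0.15 had an exact two-sided permutation p of 0.1, the smallest possible with 3 against 3 arrays, and 368 of the 441 genes were larger under 7378K light. For the 307 risen genes alone the difference was 0.14 (exact p = 0.1). For the 134 fallen genes alone it was 0.17 (exact p = 0.3), and the arrays of the groups overlapped. Without 2954K 2, the LED array with a 3' minus 5' difference like that of the controls, the difference was 0.084, and 0.069 for the fallen genes, so part of it went with that array. Per array the mean was 0.93, 0.73 and 0.94 under 2954K and 1.05, 1.01 and 0.999 under 7378K light.

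The fourth comparison set the mean of both LED groups against control. A gene can pass it through a change in 1 group alone. Microglial, gliosis and stress signalling, complement and interferon genes were higher in the mean of the LED groups, and rod genes were lower, as lists in camera. With an estimated correlation the first 2 of these lists passed, and complement (adjusted p = 0.140), interferon (adjusted p = 0.189) and rod genes (adjusted p = 0.218) did not. Edn2 rose 43.2-fold (adjusted p = 3.1e-07), Fgf2os 19.4-fold (adjusted p = 4e-08), Cebpd 16.5-fold and Socs3 12.6-fold, and Bcl3 was at least 9.43-fold and C1qc at least 6.27-fold higher. Prss56 fell by 3.03, Glb1l3 by 1.89, Dleu7 by 1.62, Nnat by 1.51, Slc25a25 by 1.5 and Slc29a1, a nucleoside transporter, by 1.30 on the log2 scale. The mean of Prss56 lay below the intensity filter in both LED groups, so the size of its fall is uncertain. Gfap rose 2.37-fold (adjusted p = 0.012, and 0.051 without control 1), Stat3 3.21-fold, Cp 2.44-fold and Aif1 at least 2.05-fold, while Opn1mw fell by 0.56 (adjusted p = 0.041, and up to 0.221 without control 2).

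Here limma called 441 genes, 307 risen and 134 fallen, with 106 and 14 of at least 2-fold, and 2753 genes had an unadjusted p under 0.05, where 638 were expected. The groups did not overlap for 1342 genes (10.5%, where chance gives 2.38%). The count was 189 without control 1, 164 without control 2, 1847 without 2954K 2, 266 without 7378K 1, 285 without 7378K 3 and 153 with the 3' minus 5' difference as a covariate. That covariate ended the calls of 22 of the 49 named genes called, namely C1qc, Aif1, Icam1, Cp, Gfap (adjusted p = 0.144), Ccn1, Vcam1, Clu, Hk1, Aqp4, Xbp1, Ern1, Isl1, Rom1, Hk2, Cnga1, Cngb1, Psmb7, Opn1mw, Slc29a1, Slc25a25 and Nnat. The dap covariate ended 24, these and Bst2 and Dleu7. Gnat1 and Sag were again without change past the test (adjusted p = 0.995 and 0.982), and Hmox1 (adjusted p = 0.0501), Opn1sw (0.40) and Arr3 (0.14) did not pass. The calls of Slc29a1, Nnat, Slc25a25, Cp and Aif1 ended in 3, 2, 2, 6 and 2 of the 9 fits that left out 1 array, up to an adjusted p of 0.171 for Cp without control 2.

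Of 21 gliosis and stress signalling genes 15 rose and of 18 microglia and macrophage genes 11 rose, with 0 fallen in both lists (18 and 15 risen when adjusted over the list alone; 9 and 8 with the 3' minus 5' difference as a covariate). The medians were 1.63 and 1.56, and 1.67 and 1.51 with the covariate. Both lists passed camera, at adjusted p = 2.9e-22 and 2.3e-16, and were the only 2 of 30 to keep an adjusted p under 0.05 with an estimated correlation, at 0.039. Of 21 interferon response genes 6 rose (14 when adjusted over the list alone) and of 7 complement genes 5 rose (5 when adjusted over the list alone), at camera adjusted p = 1.8e-07 and 2.4e-07, and adjusted p = 0.189 and 0.140 with an estimated correlation. With the covariate 4 interferon response and 3 complement genes rose, and with the dap covariate 3 and 3. Rod genes fell in 5 of 29 cases (7 when adjusted over the list alone; 2 with the covariate), namely Cnga1 by 1.32-fold, Cngb1 by 1.44-fold, Rom1, a disc protein, by 1.29-fold, Reep6 by 1.36-fold and Rgs9bp, an anchor of the transducin-inactivating complex that was named after its values were seen (camera adjusted p = 1.8e-07, and adjusted p = 0.218 with an estimated correlation). The median of the list was -0.18, and -0.28 with the covariate. The calls of Cnga1, Cngb1, Rom1 and Reep6 ended in 2, 2, 5 and 6 of the 9 fits that left out 1 array, with adjusted p of 0.096, 0.120, 0.173 and 0.145 without control 2. A further 8 lists passed camera and 17 did not (adjusted p from 0.0546 to 0.963).

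The differences of the LED groups from control were set beside each other across genes. Of the genes risen against control, 126 were shared between the 132 under 2954K and the 301 under 7378K light, and of the fallen genes, 23 were shared between 24 and 148. All 149 shared genes had the same sign. Independent calls would share 3.11 and 0.278 genes, values that do not allow for the controls both comparisons share, and no overlap was simulated. Across the 12765 genes, which are not independent replicates, the log2 differences had a Pearson r of 0.789 and a covariance of 0.120, beside 0.501 and 0.031 in simulated unchanged groups with the same controls. Without 2954K 1, the array with the highest 3' minus 5' difference (2.78), r was 0.651. The same sign was seen in 79.4% of genes, beside 66.7% in the simulations. The controls are shared by both differences and, being 3, could not be split into separate sets of 2. The 3' minus 5' difference was also higher in both LED groups, which the simulation does not allow for.

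**Figure D4:**
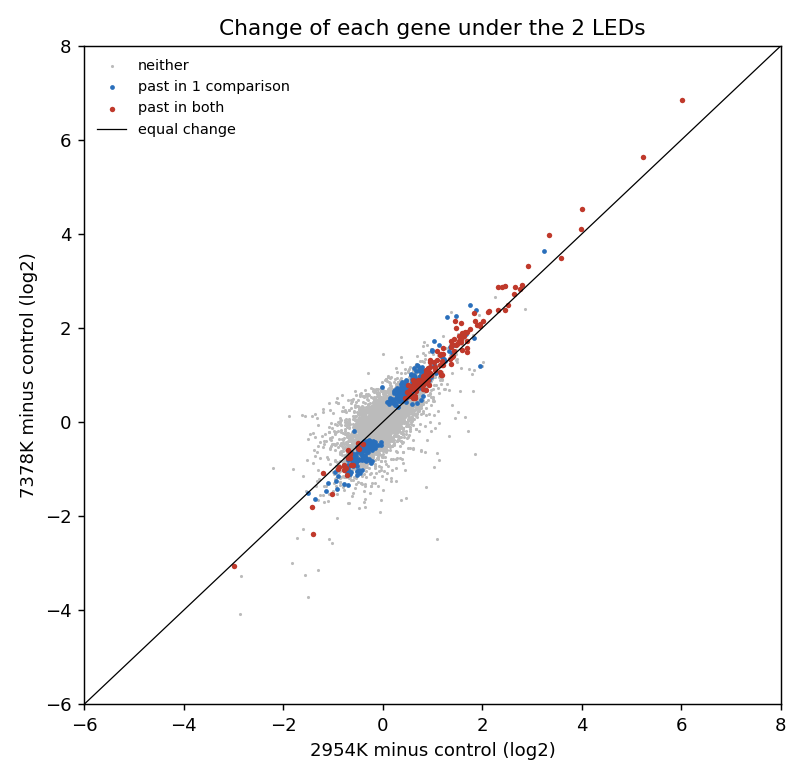
Each point is 1 of 12765 genes, with the log2 difference of 2954K from control on the x axis and that of 7378K from control on the y axis; colours mark genes changed in neither, one or both comparisons, and the line marks equal change. The 149 genes changed in both have the same sign in both.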

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

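The tests of lens tissue, of a light response of the crystallins, of degraded RNA and of the labelling reaction, and the covariate fits, were chosen only after the results were seen.

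The LED groups differed in 7 gene lists by camera in 7378K against 2954K (2 without 2954K 1, 11 without 2954K 2, 4 without 7378K 1 and 3 without 7378K 2). Cholesterol synthesis (adjusted p = 2.89e-05, 14 of 16 genes lower), pigment epithelium and melanocyte (2.89e-05, 13 of 14), rod (0.000525, 22 of 29), scleral and choroidal connective tissue (0.0160, 7 of 8) and retinoid cycle genes (0.0293, 12 of 15) were lower under 7378K light. Gliosis and photoreceptor stress signalling (0.0231, 18 of 21) and chemokine and cytokine genes (0.0259, 13 of 14) were higher. With an estimated correlation the lowest adjusted p of the lists was 0.667.

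Probe sets without a gene symbol, which stood outside the gene comparisons, also held calls. Of 3772 tested, 7 changed under 2954K light, 44 under 7378K light and 18 in the mean of both LED groups against control. Of these, 6, 30 and 13 rose, and 0 differed between the LED groups by limma.

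Other splits of the arrays were set beside each count of changed genes. For 2954K against control the real split gave 156 genes and the highest other split 118, for 7378K against control 449 and 0, and the number of splits with as many genes was 1 of 10 in both, where 10 splits are too few for a share under 0.05. For 7378K against 2954K the real split gave 0 genes and the highest other split 1, so that all 10 of 10 splits gave as many by construction and nothing was tested. For both LED groups against control, 2 of the 84 splits into 3 and 6 arrays gave as many genes. This share is under 0.05, without adjustment for the other counts, and argues against chance alone. It does not exclude a structure of the arrays, since the real split was not the highest. The other of these splits gave 657 genes, beside 518 in the real one (fits of 2 groups, in place of the 441 genes of the fit of 3 groups), and set control 1, control 2 and 2954K 2 against the rest. The split with 118 genes in 2954K against control also set these 3 arrays against the others, and the remaining wrong splits there gave 0 genes. These 3 arrays had the lowest 3' minus 5' differences, so the arrays have a structure beside their groups. With that difference as a covariate the fit of 3 groups called 153 in place of 441 genes, and with that of the dap spike-in 131.

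The genes changed in 7378K against control moved together with the 3' minus 5' difference, which was 1.36 higher than in the controls. For the risen genes, 2954K 2, with a difference of 0.21 as in the controls, was set beside 7378K. Its median rise over a held-out control was 0.545 to 0.804 of that in 7378K (295, 148 and 140 genes called anew without that control). Over the 301 risen genes the median went from 0.84 to 0.75 with the difference as a covariate (0.69 with the dap covariate). It kept at least 0.647 of its size with any 1 array left out, the lowest without 2954K 1. Only 99 genes were still called (10 to 117 with 1 array left out, the lowest without 2954K 1), 61 with dap, and the cause of the lost calls was not tested. These values cannot decide on a labelling bias, because the genes were called with the 2954K arrays in the spread. A gene that follows the 3' minus 5' difference varies within 2954K and is unlikely to pass there. With all arrays 449 genes were called, beside 1517 without 2954K 1. For the fallen genes the ratio was 0.350 to 0.499 (96, 40 and 30 genes called anew), and over the 148 genes the median went from -0.70 to -0.48 with the covariate (-0.44 with dap), while that of the rod list, with 5 of them, went from -0.25 to -0.33, with 21 of the 148 still called (0 to 32 with 1 array left out, the lowest without 2954K 1), 8 with dap, so that labelling and a response to light cannot be told apart for them, with 2954K 2 as the only LED array at the level of the controls. Under the same light, 2954K 1, with the highest 3' minus 5' difference, was compared with 2954K 2. From 2954K 2 to 2954K 1 the median change was 0.18 for the 301 risen genes, with 70.1% in the direction of 7378K. For the 148 fallen genes it was -0.30, with 84.5% in that direction, from a single pair of arrays. Without control 3 the median change was 1.04 times as large for risen and 1.01 times for fallen genes, and 224 and 89 were still called. So these calls as a set did not rest on that array. The genes had been called with control 3 in the fit, where a gene set apart by 1 control has a wide spread and is unlikely to pass. The ratio therefore cannot decide on tissue carried over in control 3, and carry-over in other pools was not tested. A response to LED light stays open, as a hypothesis, for the risen genes, and how much of their size comes from labelling is not known.

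Crystallin genes stood out in control 3 and 2954K 3, with a median excess of 8.45 and 5.98 over the other 7 arrays on the log2 scale. The highest control array lay 2.40 above the highest LED array in the mean of the crystallins, so the excess of control 3 was no response to LED light. For the LED arrays this comparison cannot decide, because it rests on 1 control pool whose high value had been seen before. Lens tissue carried into these pools is a candidate explanation: the lens fibre genes Grifin, Lim2 and Bfsp2, which are not crystallins, were higher in the same arrays, by a median of 4.81 in control 3 and 1.74 in 2954K 3. The intensity filter used the mean over all 9 arrays, and Grifin and Lim2 passed it only through control 3. A high value in that array was thus favoured by the filter. The abundant lens transcript Cryaa measured 14.66 and 11.76 there, and of the 13 measured lens genes 2, Cryab and Crybb3, lay above the intensity filter in the mean of the 6 arrays other than the third of each group. In 7378K 3 the crystallin excess was 3.38, with Cryaa at 9.80, but the lens fibre genes were 0.93 higher, beside 0.65 in 7378K 1, so that they did not set that array apart.

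The dap spike-in, a control outside the gene comparisons, had a 3' minus 5' difference that was 1.14 higher in 7378K than in control (2.75 ± 0.04 and 1.61 ± 0.22, SD, n = 3; exact two-sided permutation p = 0.1, the smallest possible). Since the spike-in is no retinal RNA, the value of 1.14 argues against degraded retinal RNA alone as the source of the difference in Gapdh and beta-actin. A difference in the labelling reaction may account for it, as the dap values of the groups did not overlap. In the 2954K arrays dap measured 3.02, 1.34 and 2.19, so the spike-in differed within that group as well. No biological explanation was tested, and for 7378K a labelling batch would coincide with the group.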

How the results depend on the processing

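The fits without 2 arrays together and those with a covariate were chosen only after the results were seen; the others were planned. The named genes called kept their direction in 784 of 784 values under the alternatives for 2954K, 1235 of 1239 for 7378K and 1189 of 1192 for both LED groups. Values of all named genes that kept their direction and lost no call numbered 3136 for 2954K and 2950 for 7378K. They numbered 3285 for 7378K against 2954K and 2890 for both LED groups. Calls gained under an alternative were not counted apart from these. In the same order, 119, 243, 0 and 188 values lost their call, and 48, 54, 94 and 69 that were no calls changed sign. With the mean of a gene's probe sets the sign reversed under 7378K light for Vcam1 (-0.27), Hk1 (-0.58) and Isl1 (-0.11). For the mean of both LED groups it reversed for Hk1 (-0.54) and Isl1 (-0.059). With x_at and s_at probe sets left out it reversed for Xbp1 in both of these comparisons (-0.26 and -0.24). For Xbp1 another probe set then stood for the gene, and for the others the mean of all its probe sets did. Leaving out 1 array ended the call of 11 of 31 named genes under 2954K light, 24 of 49 under 7378K light and 23 of 49 for the mean of both, with adjusted p of 0.051 to 0.221.

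For 2954K against control (156) the counts of changed genes were 82 with the mean of the probe sets, 101 without a trend, 384 with array weights, 558 at an unadjusted p under 0.05 with 1.5-fold, 103 without control 3 and 2954K 3, 102 with the 3' minus 5' covariate, 68 with only the groups compared, and 79 to 895 with 1 array left out. For 7378K against control (449) they were, in that order, 255 (128 risen and 127 fallen), 207, 2688 and 962, then 136 with the 3' minus 5' covariate, 77 with that of dap, 2174 with only the groups compared, and 144 to 1517 with 1 array left out. For 7378K against 2954K (0) they were 135 at the unadjusted threshold and 0 to 29 with 1 array left out. For the mean of both LED groups (441) they were 245, 265, 1940 and 681, then 153 and 131 with the covariates, and 164 to 1847 with 1 array left out. After centring on array medians 81.5% of the genes called for the mean of both LED groups rose, beside 69.6%.

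Counts of lists past camera were 14, 11, 7 and 13 for 2954K, 7378K, 7378K against 2954K and both. They were 2, 0, 0 and 2 with an estimated correlation and 7, 10, 0 and 9 with fry. For 2954K the count was 8 without control 3 and 2954K 3, and for 7378K it was 17 with the dap covariate. For 7378K against 2954K they were 4 with the 60th percentile filter, 3 with the mean of the probe sets and 3 with each probe set by itself. With 1 array left out they ranged from 9 to 14 for 2954K and from 2 to 11 for 7378K against 2954K. The correlation of the LED effects (0.789) was 0.586 without an intensity filter and 0.651 to 0.821 with 1 array left out. The cause of these shifts was not tested. Fits of fewer arrays have fewer degrees of freedom, which alone cannot account for shifts in both directions. For 7378K against 2954K, 11 lists passed without 2954K 2 and 2 without 2954K 1. For 7378K against control, where the 2954K arrays enter only the spread, 1517 genes were called without 2954K 1, beside 449. Same-number arrays deviated together, with a correlation above 0.1, in 5 of 9 pairs (0.06 to 0.33), other-number pairs reached at most 0.092, and 7 of 9 arrays correlated best with their own number, a hint from the data and not from the design, so the numbers were not used for pairing. Replicate numbers as a block gave 163, 638, 0 and 622 genes and 14, 11, 8 and 14 lists, within 1.5 times the counts without a block. Pseudocounts did not apply to values already on a log scale, and fits of only the groups compared did not apply to both LED groups. Without detection calls, signal over background is unknown for genes near the filter, such as Bcl3, C1qc and Aif1 in controls and Prss56 under LED light.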

Other observations

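The arrays compared for genes of neighbouring tissues and the probe sets of the Fgf2 locus were chosen only after the results were seen.

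Pigment epithelium and melanocyte genes moved apart between pools. Melanocyte genes were highest in 2954K 3, with Dct, a melanin synthesis enzyme, at 13.22, Pmel, a structural protein of melanosomes, at 11.59 and Mlana, a melanosome protein, at 10.56. In the same array the visual cycle gene Rpe65 was at 9.92, beside 11.23 and 11.83 in 2954K 1 and 2954K 2, and Rdh5, a retinol dehydrogenase of the pigment epithelium, was at 9.95, beside 11.62 and 11.34. In control 3 both kinds were high, with Dct at 12.19 and Rpe65 at 11.67. The connective tissue genes Dcn and Col3a1 were at 8.61 and 8.27 in control 3 and at 9.73 and 8.62 in 2954K 3, and the muscle genes Acta1 and Ckm were at 9.52 and 8.56 in control 3, beside 7.61 to 7.78 and 6.61 to 6.89 in the other controls.

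Transcripts of the Fgf2 locus were higher in LED pools, beside the antisense transcript Fgf2os. Nudt6, which overlaps Fgf2 in the RefSeq annotation of GRCm38.p6, measured 9.37 ± 0.29 in control, 12.02 ± 0.12 under 2954K and 12.25 ± 0.13 under 7378K light with one probe set (adjusted p = 1.2e-06 and 4.7e-07), and 7.40 ± 0.34, 8.43 ± 0.33 and 8.43 ± 0.18 with the other (log2 signal, SD, n = 3). Nudt6 was named here after its values were seen.

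Cone genes did not move as a group. Gnb3 rose by 0.98 under 2954K and 1.02 under 7378K light, while Opn1mw differed from control by -0.61 and -0.51 and Arr3 by -0.51 and -0.70, which did not pass. The directional test fry gave the cone list an adjusted p of 0.583 for 2954K and 0.325 for 7378K, its mixed form, which asks whether genes change in either direction, one of 5.7e-06 and 2.9e-06, and camera one of 0.983 and 0.997.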
